A study of Escherichia coli str. K-12 substr. MG1655 with 11 samples.

How the data were processed

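ChIP-exo libraries were made from Escherichia coli K-12 MG1655 grown in minimal medium with 0.2% glucose at 30 °C to an OD600 of 0.6. Per the labels' protocols, heat shock was given by adding the same volume of medium at 55 °C, unshocked cultures received medium at 30 °C, and crosslinking with 1% formaldehyde for 30 min followed 5 min later. σ32 was precipitated from a strain whose rpoH carries 8 copies of the myc epitope, with an antibody against myc. RNAP was precipitated from the untagged strain with an antibody against its β subunit, and mock precipitations used normal IgG. The samples fell into 6 groups: 2 immunoprecipitations and 2 mock precipitations for σ32 at 30 °C, the same numbers for σ32 at 42 °C, and 2 immunoprecipitations and 1 mock precipitation for RNAP at 42 °C.

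The deposited files give, per condition, 1 track with a score per base and strand, which the authors made from the immunoprecipitated and mock samples of that condition by background subtraction, per the file headers and the labels. The labels name the same track for every replicate and mock sample of a condition, so the replicates are merged in it. The submitters' processing notes name CASAVA 1.4; the aligner and its settings are not given in the sources used here. Reverse-strand scores are written below 0 and forward-strand scores above 0 in all 3 tracks, with 0 exceptions, and bases without excess over the mock are left unlisted, so a deficit against the mock cannot be seen. Listed bases numbered 687246 for σ32 at 30 °C, 1190256 for σ32 at 42 °C and 1899232 for RNAP. The position of a score is the start of a read on that strand, as ChIP-exo requires, and no shift or extension was applied here.

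The depth behind the scores was read from their low values. The most frequent steps were 1.00, 0.824 and 0.495 for σ32 at 30 °C, σ32 at 42 °C and RNAP, and 76.7%, 91.1% and 89.4% of the scores up to 25 steps were whole multiples of them within 0.005. A region's score divided by this step is called its number of steps, and counting intervals take 1 step as 1 read. This is an inference from the values. The 42 °C track has 2580533 steps, and any 2 myc libraries of the mapping summary have at most 2177563 mapped reads. If the track was made from 2 of these libraries, the numbers argue against 1 step being 1 read in the 42 °C track. The 30 °C track, with 1197913 steps, lies below that number of reads and gives no such argument. A second step of 0.859 for σ32 at 30 °C and of 1 for σ32 at 42 °C explained most of the remaining scores, and none could be told for RNAP. The deposited read counts come from a mapping summary, which gives mapped, unmapped and total reads for 8 libraries, made with myc antibody or IgG. The library names hold no temperature or sample title. The title of the summary holds Sigma-H-30, which does not tell the 8 libraries apart, so they were given to no sample. Mapped reads ranged from 684205 to 1104464 in the 4 myc libraries (50.0% to 65.3% of all reads) and from 341401 to 1349333 in the 4 IgG libraries (28.4% to 85.6%).

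The reference length was 4639675 bp in the mapping summary, without a sequence version. The only annotation at hand belongs to another build (assembly ASM584v2), so no gene was named by position and no coordinate was converted. The following planned parts were for this reason not run: σ32 ratios at gene starts, the ratio to RNAP at gene starts and the search for the σ32 promoter sequence. The gene lists fixed beforehand, with 116 members in all, were likewise not evaluated.

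The absolute values of the scores were used, with the strand kept apart. The plan had been to set values below 0 to 0, and this was not done because the sign marks the strand. Each track was scaled to the same total of 1000000 and summed in bins of 100 bp. A bin counted as occupied at 10 times the mean of all bins, occupied bins within 100 bp were joined, and each strand had to hold at least 10% of the joined score. Places that passed the level but not the strand rule are called one-sided. Levels are given as multiples of the mean score per base. Ratios between temperatures are log2 ratios of levels with 0.1 times the mean added to each, so they understate changes at low levels. Their 95% intervals come from the steps of both tracks after background subtraction, so the counting error of the mock is left out. Reads made by PCR are not independent molecules, so the intervals cover counting error of these steps only. Fold values are these ratios on the linear scale.

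The rule for regions singled out was fixed before the data were examined. It took the 10 occupied σ32 regions with the most score at 42 °C, the 5 with the most at 30 °C, the 5 largest and the 5 smallest ratios among regions occupied at either temperature, and the 10 RNAP regions with the most score. The 5 strongest RNAP regions outside the blocks of copied profiles were added after seeing the data, as were the comparison of ratios region by region in place of gene starts, the threshold of 2 times for a higher region, the 25% level for the weaker strand and other regions named as examples of strand balance or neighbouring RNAP. RNAP regions were called copies when the profile within 100 bp of their highest base matched another region at a correlation of 0.9 or more in either orientation, and copies were joined into blocks across gaps of up to 2000 bp when at least 4 regions took part.

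Overlaps of at least 1 bp were counted and set beside 1000 random circular shifts. RNAP levels in σ32 regions were set beside 10000 lists of random places of the same lengths. The distance between strand borders was the offset between −100 and 200 bp at which the product of forward and reverse score was highest, with a range from 1000 resamplings of the regions. None of these is a test over samples. Alternatives covered the level, the bin width, the strand rule, the reference for the level, the overlap, the scaling, the pseudocount, the region width and the choice of strand.

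The procedures were tested on simulated tracks with 200 planted regions, 50 of them one-sided. At 15 times the mean 48.7% of the two-sided regions were found, and at 60 times 100.0%, so that regions near the level are missed in part. No one-sided region passed (0 of 50), and 0 regions appeared that had not been planted. Both counts were largely set by the simulation. Its background was capped below the level required, and its one-sided regions had reads added on 1 strand only. They do not measure false calls in the real tracks. A planted 4-fold difference was recovered as a log2 ratio of 1.81 and a border distance of 60 bp as 62 bp. Of the copied profiles 18 of 18 were recognised, but these were exact copies, unlike noisy real ones. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.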

Results

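The binding of σ32 and of RNA polymerase (RNAP) to the chromosome of Escherichia coli K-12 MG1655 was measured by ChIP-exo before and after heat shock. σ32, the product of rpoH and named SigH in the labels, is the sigma factor that directs RNAP to heat shock promoters. In ChIP-exo, protein crosslinked to DNA is immunoprecipitated and λ exonuclease trims each DNA strand from its 5′ end up to the protein, so that read starts on the forward and the reverse strand mark the borders of the protein. Cells grown at 30 °C were brought to 42 °C for 5 min, or were kept at 30 °C for the same time. σ32 was precipitated through 8 copies of a myc tag at both temperatures, and the β subunit of RNAP was precipitated with its own antibody at 42 °C only.

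There were 11 samples. For σ32, 2 immunoprecipitations and 2 mock precipitations with normal IgG were made at each temperature. For RNAP there were 2 immunoprecipitations and 1 mock precipitation. The authors merged the samples of a condition into 1 background-subtracted track with a score per base and strand, which gave 3 tracks. The replicates were not kept apart, so no value has a replicate error, no p-value is given, and the 95% intervals cover counting error only. The total score was 1197674 for σ32 at 30 °C, 2127133 for σ32 at 42 °C and 6777176 for RNAP. The lowest scores fell on regular steps, and in units of 1 step the tracks held 1197913, 2580533 and 13691264 steps. Whether 1 step stands for 1 read was not settled. The 2 σ32 tracks hold 3778446 steps. The 4 myc libraries of the deposited mapping summary hold 3730299 mapped reads and were given to no sample. If the tracks were made from these libraries, the numbers argue against 1 step being 1 read in at least 1 of the 2 tracks. The intervals take 1 step as 1 read and are too narrow if a read makes more than 1 step. They also leave out the counting error of the subtracted mock. All levels are given as multiples of the mean score per base of the same track. Positions refer to the authors' reference of 4639675 bp, whose gene annotation was not used here, and regions are named by their position alone.

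The first comparison asked where σ32 sat before and after heat shock. At 42 °C, σ32 occupied 32 regions, and at 30 °C it occupied 9. Of the 36 regions found at either temperature, 19 were at least 2 times higher at 42 °C, with a median of 5.23 times and a range of 2.17 to 7.56 times. In the other 17 regions the level at 42 °C lay between 0.536 and 1.68 times that at 30 °C. No region fell in the gap between the 2 sets, whose nearest members had log2 ratios of 0.75 and 1.12. This gap narrowed to 0.64 and 0.78 when regions were widened by 100 bp, and on the weaker strand alone the sets overlapped (lowest of the 19 at 0.58, highest of the 17 at 1.70).

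The strongest σ32 region lay at 692601–692800. It reached 56.0 times the mean at 42 °C and 9.93 times the mean at 30 °C, a log2 ratio of 2.48 (interval 2.36 to 2.63, from 6224 and 513 steps). It was the only one of the 19 regions that was also occupied at 30 °C. The region at 1860601–1860700 followed with 51.7 times the mean at 42 °C against 7.30 at 30 °C, and 458001–458100 with 38.0 against 7.33. The region at 3325701–3325800 had 32.2 times the mean at 42 °C and 4.44 at 30 °C. At 4368501–4368700 the levels were 24.2 and 4.38, and at 3527001–3527200 they were 23.9 and 3.08. The region at 12001–12200 had 16.4 times the mean after heat shock and 2.78 before, and that at 494201–494600, the widest of the set, had 14.3 and 3.60. The last of the 10 regions with the most score among those that passed the strand rule at 42 °C were 4429001–4429200 at 14.5 against 4.69 and 1338101–1338300 at 13.2 against 2.69.

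**Figure D1:**
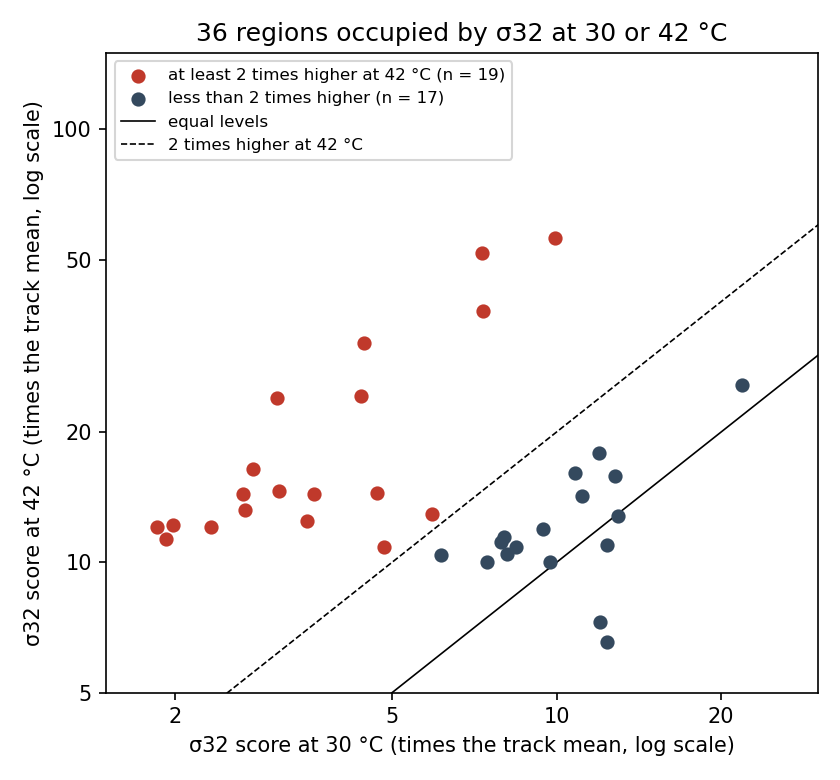
Level of σ32 at 30 °C (x axis) and at 42 °C (y axis) in the 36 regions occupied at either temperature, in multiples of the mean score per base of each track, both on log scales, with 1 point per region. The 19 regions at least 2 times higher at 42 °C (red) lie apart from the other 17 (dark blue), of which 13 lie above the line of equal levels and 4 below it.

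The log2 ratio was largest, at 2.92 (2.73 to 3.20), at 3527001–3527200, and was 2.83 (2.58 to 3.14) at 3325701–3325800 and 2.81 (2.61 to 3.05) at 1860601–1860700. It was 2.63 (2.27 to 3.15) at 4120301–4120400 and 2.56 (2.21 to 3.06) at 661901–662000, where the 30 °C track held 48 and 51 steps. Of the 19 regions, 14 were at least 4 times higher at 42 °C. Over all 36 regions the counting interval of the log2 ratio lay above 0 in 31, below 0 in 3 and across 0 in 2. These counts were the same with 2 steps taken as 1 read. They partly reflect the selection, since 32 of the 36 regions were selected by their level at 42 °C, which favours ratios above 0. The 3 regions with intervals below 0 were all occupied at 30 °C only.

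Most of the strongest regions at 30 °C were less than 2 times higher on heat shock or were lower. Ranking regions by their level at 30 °C in itself favours low ratios. The region at 1614201–1614300 had the highest level at 30 °C among regions that passed the strand rule, with 21.8 times the mean, and had 25.7 times the mean at 42 °C, a log2 ratio of 0.23 (0.09 to 0.38). At 2102801–2102900 the levels were 12.8 and 15.8, a log2 ratio of 0.31. The region at 4422801–4423100, which held the most score of any region at 30 °C, had a log2 ratio of −0.17 (−0.29 to −0.06). The lowest ratio was that of 3809801–3810000, which went from 12.3 times the mean at 30 °C to 6.56 at 42 °C, a log2 ratio of −0.90 (−1.07 to −0.76). It was followed by 2631801–2631900 at −0.71 (−0.93 to −0.50). The ratios of 1225801–1225900 (−0.02) and 4124901–4125000 (0.04) had intervals that held 0.

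**Figure D2:**
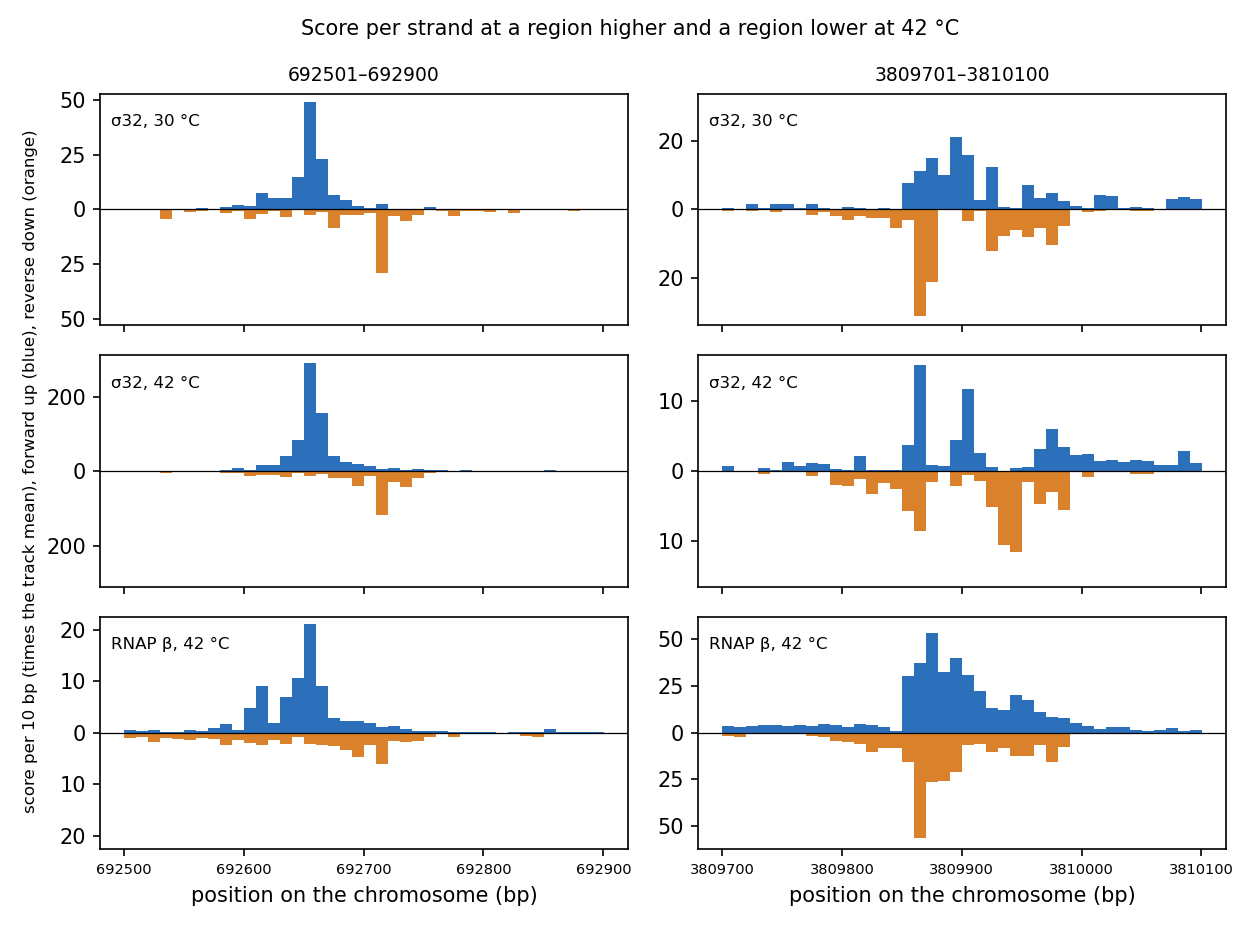
Score in bins of 10 bp around the region with the highest level at 42 °C (692601–692800, left) and the region with the lowest ratio (3809801–3810000, right), in multiples of the track mean, with forward-strand score upward (blue) and reverse-strand score downward (orange), each panel with its own y scale. On the left the highest forward base (692656) lies 55 bp to the left of the highest reverse base (692711). On the right the order is the same, with the highest forward base (3809869) 72 bp to the left of the highest reverse base (3809941).

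The occupied regions at 30 and 42 °C overlapped in 5 cases out of 9. These were 692601–692800, 1614201–1614300, 2102801–2102900, 3664001–3664100 and 3670101–3670200. In 1000 random shifts of the regions around the chromosome the mean overlap was 0.018 and the highest was 1. Before the rule that each strand must hold at least 10% of the score, 58 of the 69 places that passed the level at 30 °C also passed it at 42 °C. Across 46396 bins of 100 bp the levels at the 2 temperatures had a Spearman rho of 0.83 (bins are not independent replicates).

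The counts of regions moved with the level required. At 5 times the mean, 165 regions were found at 42 °C and 151 at 30 °C, and at 20 times the mean 7 and 1. The number past a ratio of 2 moved with the scaling: without scaling, which adds 0.82 to each log2 ratio, 31 regions were at least 2 times higher, and of the 4 ratios below 0 only 1 stayed there, or 2 with scaling to the median of the background.

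The regions with more σ32 at 42 °C also differed in shape from the rest. In the 19 regions that were at least 2 times higher, the weaker strand held a median of 36.7% of the score at 42 °C, and in 16 of them it held at least 25%. In the other 17 regions the median was 19.5%, and 6 had at least 25%. At 4440201–4440300 the weaker strand held 6.97% of the score at 42 °C, whereas at 1027901–1028000 the 2 strands were nearly even at 49.8%. Over all 36 regions the log2 ratio and the share of the weaker strand had a Spearman rho of 0.57.

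Summed over regions, the forward and reverse borders lay about 60 bp apart, with a wide spread between single regions. The product of forward and reverse score over the 32 regions at 42 °C was highest at 60 bp (60 to 69 when regions were resampled). In the 19 higher regions it was also highest at 60 bp (60 to 69), and in the other 17 at 61 bp with an interval of −80 to 132. In the 9 regions at 30 °C the maximum lay at 58 bp (−90 to 116) and was not resolved. The highest forward base lay to the left of the highest reverse base in 17 of the 19 higher regions and in 12 of the other 17. In the 19 this distance had a median of 52 bp and a range of −197 to 151 bp. It was 60 bp at 3865501–3865600, 52 bp at 4368501–4368700, 3 bp at 458001–458100 and 151 bp at 12001–12200.

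**Figure D3:**
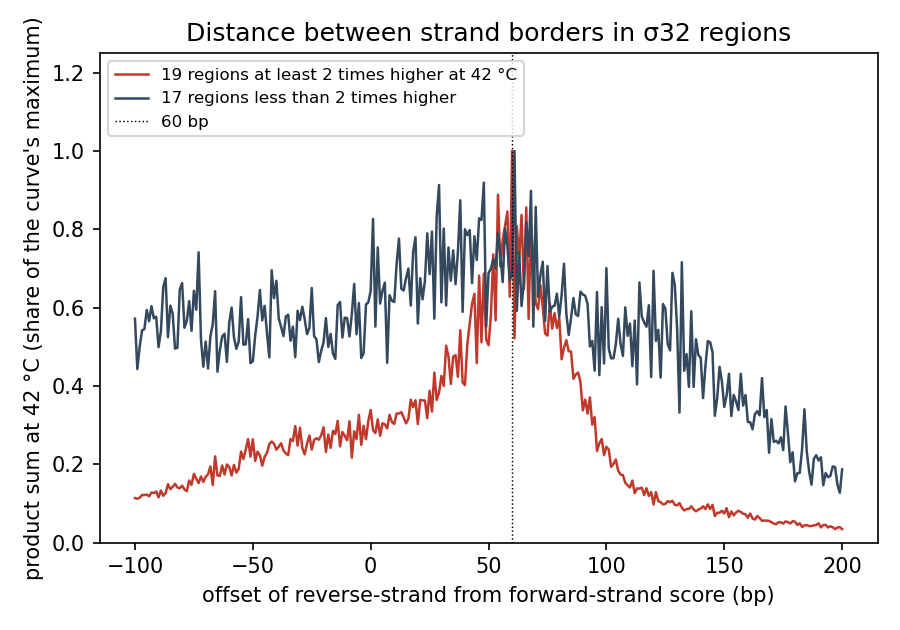
Product of forward-strand and reverse-strand score of the 42 °C σ32 track as a function of the offset between the strands in bp, as a share of each curve's maximum, for the 19 regions at least 2 times higher at 42 °C (red) and the other 17 (dark blue). The red curve has its maximum at 60 bp, and the dark blue curve is broad with its maximum at 61 bp.

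The second comparison set σ32 beside RNAP at 42 °C. RNAP was at least 2 times its mean in 28 of the 36 σ32 regions and under its mean in 2. The 32 regions occupied at 42 °C had a median RNAP level of 4.08 times the mean. In 10000 lists of random places of the same sizes the median was 0.259 and the highest value 0.689. A raised RNAP level was not particular to these regions. The one-sided σ32 places of 42 °C had a median RNAP level of 2.73 times the mean, and those of 30 °C had 5.18. Across all bins σ32 at 42 °C and RNAP had a Spearman rho of 0.54. The 19 higher regions had a median RNAP level of 4.15 times the mean, and the other 17 had a higher one of 9.0.

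Among the 19 higher regions, RNAP was highest at 458001–458100 with 14.3 times its mean and at 1860601–1860700 with 14.3. The region at 494201–494600 had 9.24 times the RNAP mean, 12001–12200 had 6.92 and 692601–692800 had 5.84. The region at 2386401–2386500 had 0.545 times the RNAP mean beside 10.8 times the σ32 mean. A flank of 2000 bp with RNAP at 2 times its mean or more lay beside 8 of the 19 higher regions and beside 6 of the other 17. In the 17 it reached 10.7 at 4124901–4125000 and 9.41 at 3937901–3938000. The flank of 3937901–3938000 runs into the block of copied profiles at 3939601–3944500, where levels are uncertain. In the 2000 bp above 12001–12200 RNAP averaged 15.8 times its mean, and in the 2000 bp below 0.230. At 4368501–4368700 the values were 14.6 above and 1.59 below, and at 494201–494600 RNAP averaged 5.81 above. At 3865501–3865600 RNAP lay on the lower side, with 4.07 against 0.305.

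The 17 regions less than 2 times higher included those with the most RNAP. RNAP reached 49.6 times its mean at 4124901–4125000, 41.9 at 2631801–2631900, 31.4 at 3809801–3810000 and 24.5 at 3664001–3664100. It was at least 10 times its mean in 8 of these 17 regions and in 2 of the 19 higher ones. Others of the 17 had little RNAP, such as 3670101–3670200 with 0.330 times the mean and 1614201–1614300 with 1.83.

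**Figure D4:**
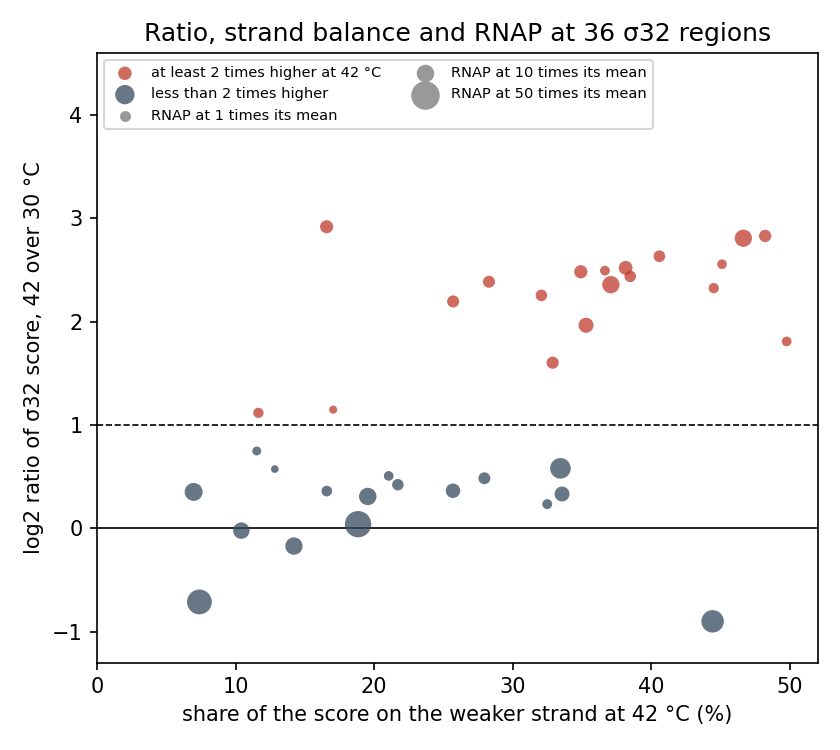
Log2 ratio of σ32 score at 42 over 30 °C (y axis) against the share of the score on the weaker strand at 42 °C in percent (x axis) for the 36 regions, with the area of each point growing with the RNAP level at 42 °C. Most of the 19 higher regions (red) have at least 25% of the score on the weaker strand, and the points with the most RNAP belong to the other 17 (dark blue).

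Of the 32 regions occupied by σ32 at 42 °C, 5 overlapped a region occupied by RNAP, against a mean of 0.509 and a highest value of 4 in 1000 random shifts. Of these, 12001–12200, 458001–458100 and 1860601–1860700 were among the 19, and 3664001–3664100 and 4124901–4125000 were not. The count fell to 0 at 20 times the mean and was 51 of 165 at 5 times the mean. At 30 °C, 4 of the 9 σ32 regions overlapped a RNAP region of the 42 °C track.

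The share of the score on the forward strand was related between the tracks of σ32 and RNAP. Over the 36 regions the Spearman rho of the forward share was 0.83 between σ32 at 42 °C and RNAP and 0.97 between σ32 at 42 °C and at 30 °C. In the 17 regions less than 2 times higher the rho with RNAP was 0.93, and in the 19 higher ones it was 0.64. The stronger strand was the same in both tracks in 16 of 17 and in 13 of 19 regions. The weaker strand held a median of 36.7% in the 19 and 19.5% in the 17 at 42 °C. The stronger strand is therefore less defined in the 19.

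RNAP occupied 151 regions at 42 °C, which held 30.2% of its score in 1.13% of the chromosome. The RNAP signal was concentrated in 7 blocks of 4800 to 5100 bp in which profiles around the highest bases recurred. The blocks lay at 223601–228500, 2724401–2729400, 3422001–3427100, 3939601–3944500, 4033301–4038300, 4164401–4169400 and 4206001–4210800. Together they held 20.3% of the RNAP score in 0.75% of the chromosome. Their RNAP level was 24.8 to 30.3 times the mean, with most score on the forward strand in 5 and on the reverse strand in 2. In the σ32 tracks they stood at 2.13 to 2.46 times the mean at 30 °C and 1.90 to 2.15 times at 42 °C, and no σ32 region that passed the strand rule lay in them. One-sided σ32 places lay in some of them, such as 3940901–3941000 with 11.7 times the mean at 30 °C and 11.4 at 42 °C, 4034601–4034700 with 11.1 and 11.4, 4207201–4207300 with 11.8 and 11.2, 4165701–4165800 with 11.9 at 30 °C and 2728001–2728100 with 10.2 at 42 °C. Over 4500 bp the best correlation of a block's RNAP profile with another block was 0.724 to 0.965. Levels in single blocks are uncertain, since no sequence was used here to tell such places apart.

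Of the 10 RNAP regions with the most score, 8 lay inside these blocks, led by 2726201–2728200 at 36.5 times the mean, 3423801–3425800 and 3940801–3942300 at 42.4. The others were 4603401–4604500 and 3944801–3945200, the latter with 88475 steps. It lay just above the end of the block at 3939601–3944500. Outside the blocks, 2922201–2922600 reached 71.8 times the mean and 4370001–4370500 reached 37.0. A further strong region at 13001–13700 and that at 4370001–4370500 lay above the σ32 regions at 12001–12200 and 4368501–4368700.

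The 117 RNAP regions outside the blocks had a median σ32 level of 2.79 times the mean at 30 °C and 2.26 at 42 °C, where random places had 0.764 and 0.670. The median log2 ratio of σ32 in these regions was −0.17, and 77 of the 117 were lower at 42 °C. The whole track shifted the same way, with a median of −0.09 over all bins, and with scaling to the median of the background the values were 0.03 in these regions and 0.08 over all bins. The number of these regions lower at 42 °C was 56 with that scaling and 16 without scaling. Over all bins the shift did not grow with RNAP. The log2 ratio was −0.04 in the 10% of bins with the most RNAP and −0.16 in those with the least. In 3 of the 117 regions (12101–12200, 458001–458100 and 1860601–1860900) σ32 was at least 2 times higher at 42 °C. The offset between the strands was not resolved for RNAP, with a maximum at 99 bp over all 151 regions and at −38 bp (−65 to 69) outside the blocks.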

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

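The RNAP track held 2 scores, summing to 172.27, that were assigned to no reference sequence and so entered no comparison. They are given because they lie outside the measurement. Only bases with an excess over the mock are listed, so their size alone tests nothing. The mock level behind them was not analysed here, and no biological explanation was tested.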

How the results depend on the processing

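All alternatives for the ratios and for their counts and intervals, shifted bins and the wider strand rule were chosen after seeing the data; the others before. No paired analysis was possible because the replicates are merged in each track, and for the same reason leaving out replicates was not run. The alternatives for gene starts and for the promoter sequence were not run, for lack of an annotation and a sequence of the same build.

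At a level of 20 times the mean there were 7 σ32 regions at 42 °C, 1 at 30 °C and 79 RNAP regions; 1 was shared between temperatures and 0 between σ32 and RNAP. At 5 times the mean the counts were 165, 151 and 270, with 92 and 51 shared. Bins of 50 bp gave 50 and 28 σ32 regions, with 14 and 12 shared. Without the strand rule there were 147, 69 and 301 regions, with 58 and 43 shared. Measured against the median bin, there were 108, 43 and 579 regions, with 28 and 57 shared. Applying the strand rule with 50 bp on each side gave 17 regions at 30 °C, and with 100 bp on each side 21, with 11 shared between temperatures and 14 with RNAP. Bins shifted by 50 bp gave 8 shared with RNAP. Stricter and looser levels change the counts by construction; for the other settings the cause was not tested. The RNAP border distance turned from 99 bp to −1 bp with capped values, and the σ32 distance at 42 °C stayed between 60 and 66 bp.

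The 19 regions at least 2 times higher at 42 °C stayed the same 19 when scaled to the median of the background, when scaled without the blocks, with a larger pseudocount and without the highest base of each strand. Without scaling there were 31, since this adds 0.82 to each log2 ratio (scaling to the median adds 0.21). Among regions of the stricter level there were 6. Widening by 100 bp left 17, all among the 19, and 2 times the weaker strand gave 19, of which 18 were shared. The following signs changed: the log2 ratio of 1225801–1225900 became 0.18 with median scaling, 0.80 without scaling, 0.27 when widened and 1.70 on the weaker strand; 2631801–2631900 became 0.11 without scaling; 4422801–4423100 became 0.03 with median scaling and 0.65 without scaling; and 4124901–4125000 became −0.22 on the weaker strand. Of all alternatives for single regions, 78 stayed within the counting interval, 47 moved and 8 changed sign.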

Other observations

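The tests of scaling and of a common signal in the 17 regions less than 2 times higher, and that of the blocks, were chosen after the result was seen; the tests of the one-sided places and of the RNAP strand were chosen before. Some places with RNAP had a lower σ32 level at 42 °C than at 30 °C, in a count that moved with the scaling. In 10 of the 117 RNAP regions outside the blocks the σ32 level was at least 2 times lower at 42 °C. The count was 5 with scaling to the median of the background and 0 without scaling, and the median log2 ratio over all bins was −0.09. At 4177601–4177800 the σ32 level went from 3.03 to 0.870 times the mean, a log2 ratio of −1.69 (interval −2.18 to −1.43), while RNAP stood at 13.0 times its mean. At 4047901–4048000 it went from 5.83 to 1.87, a log2 ratio of −1.59. At 101–200, where RNAP reached 65.4 times its mean, σ32 went from 7.63 to 3.33. At 3578901–3579100, with RNAP at 34.5 times its mean, it went from 4.06 to 1.79. These values carry no replicate error, and RNAP was measured at 42 °C only.

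One-sided places outnumbered the σ32 regions. There were 115 at 42 °C and 60 at 30 °C, with score on the forward strand in 62 and 32 of them. Their median log2 ratio of 42 over 30 °C was 0.48 for those of 42 °C and 0.10 for those of 30 °C. At least 2 times higher at 42 °C were 10 and 0 of them. Each set was selected by its level at its own temperature, which favours higher ratios in the first and lower ones in the second. The highest ratio, 4.46, lay at 295601–295700, where 1 base of the reverse strand (295626) held 95.3% of the score, with 1489.98 at 42 °C and none listed at 30 °C or for RNAP.

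The 36 σ32 regions differed in how much higher they were at 42 °C. The quartiles of the log2 ratio lay 2.04 apart (0.36 and 2.40). A factor applied to a whole finished track would move all regions alike, so the spread argues against such a factor as the only cause. A difference in how the mock was weighted before subtraction need not act as 1 factor. The comparison cannot decide on that. For the 17 regions less than 2 times higher, the stronger strand was the same as in the RNAP track in 16. In the 19 higher regions it was the same in 13, but their strands were more even, so the stronger strand is less defined. Signal that both immunoprecipitations pick up could give the match in the 17, although σ32 bound together with RNAP would give the same pattern. The comparison cannot show that such signal is particular to the 17. The higher level of the other 19 at 42 °C stays open between a response to heat and a difference between single merged tracks, since temperature and library preparation cannot be separated without replicates.

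The one-sided places may likewise hold signal that both immunoprecipitations pick up. Among the 45 one-sided places of σ32 at 42 °C with RNAP under 2 times its mean, the stronger strand was the same in both tracks in 44, or 97.8%. Copies of single fragments made by PCR could put most of the score on 1 base. The highest base held at least 50% of the score in only 1 of 115 places, that at 295601–295700, and the median share was 9.9%. This speaks only against 1 dominant fragment per place and cannot tell whether several amplified fragments made up the score. No biological explanation was tested for these places.

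The 7 blocks with recurring RNAP profiles may hold reads shared between near-identical copies of a sequence. In the σ32 track at 42 °C, which was not used to find them, the profile around a highest base matched another block at 0.9 or more in 7 of 7 blocks at their best place (0.907 to 0.941). Counted by place, 7 of 37 in the blocks and 0 of 37 drawn from outside reached 0.9, with median best correlations of 0.764 and 0.51. A comparison over 4500 bp, run first, had given 0 of 7 blocks at 0.9 (0.476 to 0.706), and the shorter profile that found the blocks was turned to after that. Over 4500 bp RNAP itself passed 0.9 in only 2 of 7 blocks. Thinned to the σ32 depth, RNAP passed it in 0 (0.647 to 0.823), so the bound of 0.9 had no power to decide there. The σ32 correlations over 4500 bp still lay lower than those of thinned RNAP, with ranges that overlap. The cause of that difference was not tested. The ribosomal RNA operons, of which E. coli K-12 carries 7, are a candidate source, which was not tested for lack of an annotation of the build.

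A hypothesis on the strand of RNAP was left undecided. Where RNAP extended to 1 side of a σ32 region, the forward strand was predicted to hold more of its score on the upper side and the reverse strand on the lower side. The prediction held in 10 of the 14 regions with a RNAP flank of at least 2 times the mean. This lies between the bounds of 60% and 80% set for either answer, and 14 regions are too few to decide.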
